A study of Mus musculus with 8 samples.

How the data were processed

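Hearts of WT and Set7KO mice given saline or isoproterenol were profiled by RNA sequencing, with 2 libraries in each of 4 groups. Per the labels' protocols, libraries were made with a TruSeq stranded mRNA kit and sequenced on a NextSeq 500 with single reads of 75 cycles. The deposited values are counts per gene, 1 column per library. The submitters' processing notes name HISAT2, HISAT, StringTie and edgeR and the GRCm38 genome; versions and the role of each tool are not given in the sources used here. The deposited counts were whole numbers for 55487 gene identifiers, of which 29066 had a count in at least 1 library. Symbols and coordinates were taken from GENCODE release M21 for GRCm38, which named 55227 of the identifiers.

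Groups were taken from the labels. A model with a mean for each of the 4 groups was fitted to all 8 libraries with edgeR 4.0.16 in R 4.3.3, with TMM normalization and filterByExpr, which kept 17636 genes. Quasi-likelihood F-tests were two-sided and adjusted by Benjamini-Hochberg within each of 7 contrasts, with a threshold of 0.05. The contrasts were isoproterenol against saline in each genotype, Set7KO against WT in each treatment, the interaction, and each factor averaged over the other. The model left 4 residual degrees of freedom, with 4.36 prior degrees of freedom and a biological coefficient of variation of 28.4%. Standard errors were derived from the F statistic. Normalised CPM use the TMM library sizes, and fold changes come from the fit. A level of 3 counts was taken as the floor, 0.0598 to 0.112 CPM depending on the library.

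The contrasts, the 35 gene lists, the rule for named genes and the alternatives other than the offsets were chosen before the data were examined. The lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and with camera at an estimated correlation and fry beside it, adjusted over the lists within a contrast. Symbols absent from the annotation were matched through 8 renamed symbols, and the oxidative phosphorylation list of 51 symbols held 52 measured genes because a symbol has 2 identifiers. Members were counted after adjustment over all genes tested and over the list alone. The lists for TGF-beta signalling, apoptosis and p53 targets, and ventricular, endothelial, adipocyte, epicardial, neural and neighbouring tissue markers were not called in any of the 7 contrasts with all libraries and no offsets; with GC and length offsets endothelial markers were called in 1 (Set7KO against WT after isoproterenol, camera adjusted p = 0.013, 0.789 with an estimated correlation).

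The genes named are Setd7; for each contrast, genes past the threshold with a mean of at least 2 CPM and no overlap between the groups (no rule on overlap for the interaction), the 10 largest rises and falls, or 5 and 5 for the interaction and averaged contrasts; where none passed, the 5 smallest p-values, given as values that did not pass; up to 4 members with the smallest p at a mean of at least 1 CPM from each list named; and Nppa, Nppb, Myh7, Acta1, Col1a1, Col3a1, Postn, Eln, Wnt10a and E2f1. Gene models, clone-named genes, pseudogenes and ribosomal protein genes were left out by name. Some genes that the rule selects are not reported here. Members of the extracellular matrix, activated fibroblast, hypertrophy, TGF-beta and Wnt lists were added in contrasts where those lists were not called, after the list results were seen. Per-library levels of Il1b, S100a9, Csf3r and Ankrd1 were chosen for printing after their values were seen.

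Alternatives were other normalizations (size factors of DESeq2, upper quartile), other filters (none, or 1 CPM in 2 libraries), robust quasi-likelihood, limma-voom, DESeq2 1.42.0, fits on the 2 groups compared, an additive model, summing identifiers of a symbol, and leaving out each library. Where a group was left with 1 library, that library was assumed to vary like the other groups. The filter was applied anew in each such fit, so the set of genes tested could differ. After seeing the data, offsets per library from natural splines (5 degrees of freedom each) of GC content and exonic length were added, alone, with each Set7KO saline library left out, and in DESeq2.

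The procedure was tested on simulated counts with 200 changed genes, after the first run of the main comparisons. For isoproterenol against saline in WT (17244 genes) it called 76 genes, 4 of them unchanged, and recovered 2% of 2-fold and 70% of 4-fold changes. For the interaction (17220 genes) it called 8, 3 of them unchanged, and recovered 0% and 5%. For isoproterenol averaged over genotypes (17213 genes) it called 146, 14 of them unchanged, and recovered 34% and 98%. In each comparison, simulated once, the share of unchanged genes among the calls was above the threshold of 0.05. A simulated changed list in the WT comparison had a camera p of 1.85e-16 with the preset and 0.000727 with an estimated correlation, and an unchanged list 0.780 with the preset. These are p-values of single lists from limma. Simulated genes were drawn independently, whereas members of some real lists vary together. The simulation therefore does not test how the preset correlation behaves for such lists. All libraries shared the same spread for a gene, none stood apart, and changed genes had a mean of at least 2 CPM. The recovered shares may not hold for the real libraries, where the Set7KO saline pair differed more than the other pairs. In a further simulation with no changed gene, a linear GC tilt was set on the 2 WT isoproterenol libraries alone, and the spread was capped at a low value. There edgeR called 4727 of 17636 genes in the WT comparison without offsets and 0 with them. Neither the tilt nor the spread was that of the data, so these counts do not say how many real calls come from GC content.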

Results

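RNA from 8 mouse heart samples was sequenced in a 2-factor design of genotype and treatment. The genotypes were wild type (WT) and a global knockout of Set7 (Set7KO). Set7, encoded by Setd7, is a lysine methyltransferase that methylates histone H3 and several other proteins. The treatments were saline and isoproterenol, a beta-adrenergic agonist used to provoke cardiac hypertrophy and fibrosis, given subcutaneously at 60 mg/kg for 14 consecutive days. The comparisons address how isoproterenol changes transcript levels in the heart and whether loss of Set7 alters that response. Each of the 4 groups held 2 libraries. The libraries held between 27847069 and 51705705 counts assigned to genes. The labels do not state that each library came from a separate animal, so p-values measure the spread between these samples, part of which can be technical.

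Setd7 (ENSMUSG00000037111) lies on the minus strand of mouse chromosome 3 at 51515319 to 51560879 in GRCm38. Its level was 43.7 and 43.0 CPM (normalised counts scaled to library size) in the WT saline libraries, and 58.1 and 72.6 CPM in the WT isoproterenol libraries. In the Set7KO libraries it was 4.45 and 5.70 CPM after saline and 3.79 and 3.92 CPM after isoproterenol. Averaged over treatments, Setd7 was 12.0-fold lower in Set7KO than in WT (log2 fold change -3.59 ± 0.18 SE, adjusted p = 0.000356). The 4 Set7KO libraries lay below the 4 WT libraries without overlap, as their labels state. The labels do not say which part of the gene was deleted, so the remaining counts were not assigned to an exon.

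**Figure D1:**
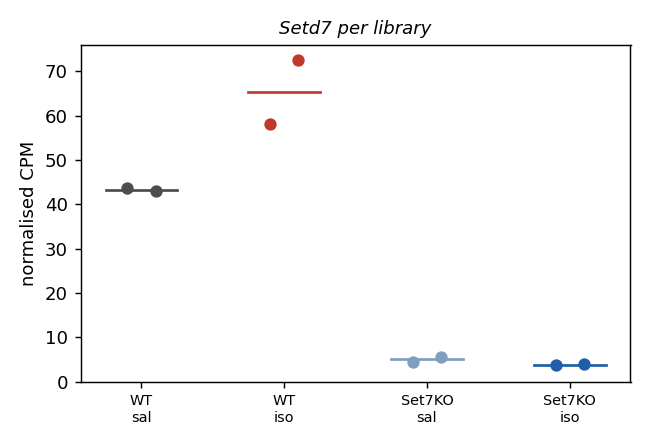
Setd7 level in normalised CPM on the y axis for each of the 8 libraries, grouped on the x axis by genotype and treatment (sal, saline; iso, isoproterenol). Points are libraries and horizontal lines are group means; the Set7KO libraries sit between 3.79 and 5.70 CPM and the WT libraries between 43.0 and 72.6 CPM.

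The libraries did not group by genotype and treatment alone. The first principal component held 45.4% of the variance. It placed the WT isoproterenol libraries (scores 67.3 and 58.6) and Set7KO saline replicate 2 (61.8) at one end and the other 5 libraries between -71.7 and -19.0. Loadings on this component correlated with the GC content of genes across genes (Spearman's rho -0.752), genes not being independent replicates. The median log2 deviation of genes in the highest GC class minus that in the lowest, of 5 equal classes, was -1.05 and -0.74 in the WT isoproterenol libraries. The same difference was -0.89 in Set7KO saline replicate 2 and 0.41 in Set7KO saline replicate 1. The 2 Set7KO saline libraries correlated at r = 0.949 across genes, against 0.968 to 0.984 for the replicate pairs of the other groups. Within WT the GC trend moved together with isoproterenol. For each contrast the number of genes past the threshold is given also with offsets for GC content and gene length, an alternative chosen after seeing the data. For lists called without offsets, medians with these offsets are given where they moved by over 1.5 times or changed sign.

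**Figure D2:**
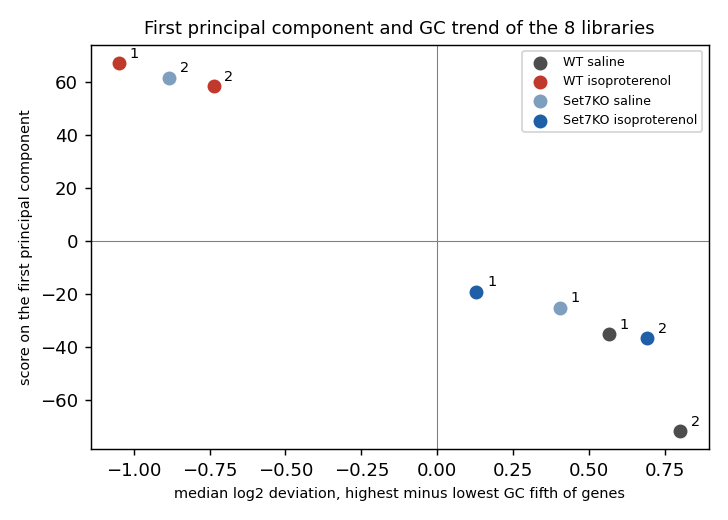
Score on the first principal component (y axis) against the difference in median log2 deviation between the highest and the lowest of 5 equal GC classes of genes (x axis) for the 8 libraries, coloured by group and numbered by replicate. The 2 WT isoproterenol libraries and Set7KO saline replicate 2 lie at scores of 58.6 to 67.3 with differences of -1.05 to -0.74, and the other 5 libraries lie below a score of 0.

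Averaged over both genotypes, isoproterenol raised 2 genes and lowered 7 of the 17636 tested. Cpxm2, which encodes a secreted carboxypeptidase-like protein, rose 3.86-fold, from 29.7 ± 8.01 CPM after saline to 112.2 ± 15.2 CPM after isoproterenol (SD, n = 4 each; log2 fold change 1.95 ± 0.16 SE, adjusted p = 0.0128). Angptl4, an inhibitor of lipoprotein lipase, fell 8.27-fold to 3.55 ± 2.43 CPM from 24.7 ± 10.3 CPM, and Scd4, a stearoyl-CoA desaturase, fell 6.34-fold to 1.51 ± 0.176 CPM from 9.69 ± 1.68 CPM. Acot1, a cytosolic acyl-CoA thioesterase, fell 3.07-fold to 12.4 ± 3.08 CPM from 37.2 ± 3.38 CPM. Fbp2, the muscle fructose bisphosphatase, fell 2.72-fold, and Scgb1c1, a secretoglobin, fell 2.86-fold.

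In edgeR's quasi-likelihood test the adjusted p was 0.0406 for Angptl4, 0.0124 for Scd4, 0.0189 for Acot1, 0.0357 for Fbp2 and 0.0357 for Scgb1c1, and each gene had non-overlapping levels in the 4 saline and the 4 isoproterenol libraries. Cpxm2 (ENSMUSG00000030862) lies on chromosome 7 at 132032687 to 132154739, Scd4 (ENSMUSG00000050195) on chromosome 19 at 44333092 to 44346743, Angptl4 (ENSMUSG00000002289) on chromosome 17 at 33773750 to 33781830, and Acot1 (ENSMUSG00000072949) on chromosome 12 at 84009490 to 84018371. Fbp2 (ENSMUSG00000021456) lies on chromosome 13 at 62836877 to 62858422 and Scgb1c1 (ENSMUSG00000038801) on chromosome 7 at 140845547 to 140846769. The other 3 genes past the threshold were chosen for naming after their values were seen: Pou3f1 (log2 fold change 2.81), Edn3 (-2.39) and the clone-named gene AC153155.1 (-2.54), each at a mean under 2 CPM. Acot1 and Scd4 belong to families of close paralogs, and how reads shared between paralogs were counted is not given in the sources used here.

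With GC and length offsets 14 genes passed, the 9 above among them, and limma-voom called 14 genes and DESeq2 235, again with the 9 among them, while an additive model in edgeR called 1 gene. The calls were not kept in edgeR without WT saline replicate 1 or 2, WT isoproterenol replicate 1 or 2, or Set7KO isoproterenol replicate 1. Most were lost without Set7KO isoproterenol replicate 2. These fits left 1 library in a group and filtered the genes anew, so the genes tested were not the same 17636. Without Set7KO saline replicate 1 or 2 the 9 genes passed in fits without offsets. With GC and length offsets as well, only some of the 9 passed, in fits where that group held 1 library.

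**Figure D3:**
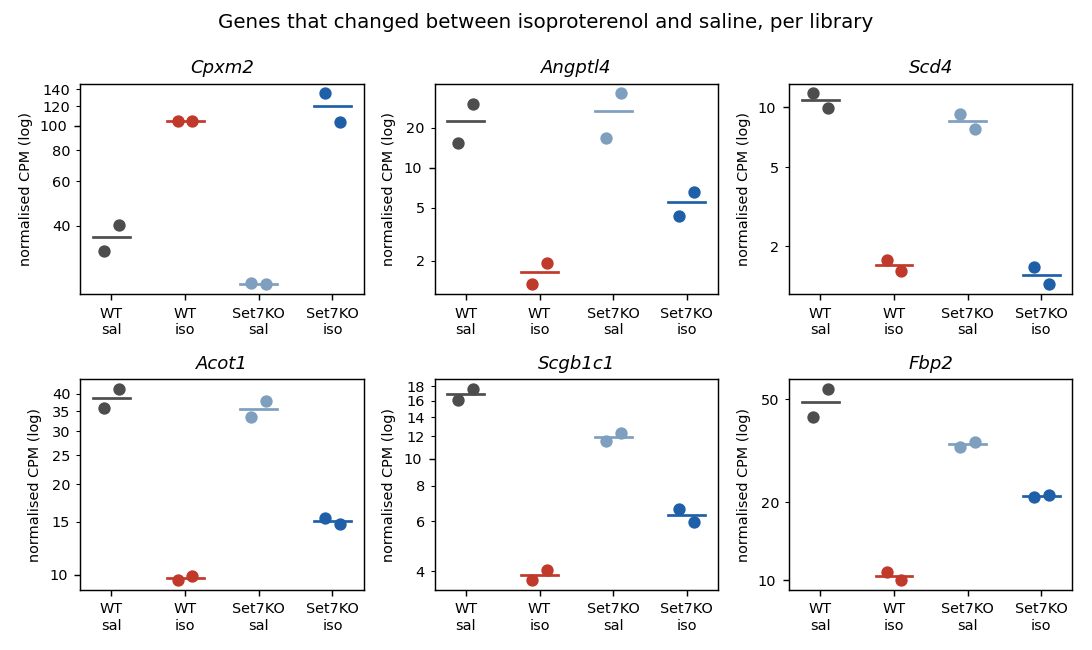
Normalised CPM on a log axis (y) of 6 genes that changed between isoproterenol and saline averaged over genotypes, for each of the 8 libraries, by group (x; sal, saline; iso, isoproterenol). Points are libraries and lines are group means; Cpxm2 lies between 104 and 135 CPM in the isoproterenol libraries and between 23.3 and 40.2 CPM in the saline libraries, and the other 5 genes are lower in the isoproterenol libraries of both genotypes.

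Several gene groups moved with isoproterenol when the genotypes were averaged. Cell cycle genes fell as a list: 22 of 42 measured members fell and 1 rose adjusted over the list alone, with a median log2 fold change of -0.98. With the difference of log2 Dbp and Arntl, 2 clock genes, as a covariate the median was -0.43. Mki67, a proliferation marker, had a log2 fold change of -2.16 ± 0.35 SE, and Top2a, a topoisomerase of dividing cells, of -2.15 ± 0.38. Fatty acid oxidation genes fell, with 15 of 35 members lower and 0 higher adjusted over the list alone and a median of -0.40. Besides Acot1, this list held the mitochondrial carrier Ucp3 (-2.03 ± 0.28) and the thioesterase Acot2 (-1.09 ± 0.15). Over all genes tested, Acot1 was the member of these 2 lists that passed; the other members named here passed adjusted over the list alone. The adjusted p of both lists was 0.359 with an estimated correlation.

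Lymphocyte, antigen presentation and erythroid lists also fell after isoproterenol, whereas macrophage (camera adjusted p = 0.193) and neutrophil (0.193) lists were not called. Lymphocyte markers had a median of -1.32, with 12 of 16 members lower adjusted over the list alone, among them Cd79a of B cells (-1.40 ± 0.30) and Trbc2 of T cells (-1.34 ± 0.33). Antigen presentation genes had a median of -0.66, and 6 of 14 fell adjusted over the list alone, led by the class II genes H2-Aa (-1.74 ± 0.29) and H2-Eb1 (-1.89 ± 0.32). Erythroid markers had a median of -1.27, with the globin genes Hba-a2 (-1.29 ± 0.28) and Hbb-bs (-1.32 ± 0.29) among 6 of 8 members lower adjusted over the list alone. Immediate early genes (median -0.53, 6 of 24 lower), NF-kB and cytokine genes (-0.40, 3 of 33 lower), oxidative phosphorylation (-0.16, 0 of 52) and ER stress genes (-0.12, 3 of 20 lower) fell as lists. The counts are adjusted over each list alone. Their adjusted p with an estimated correlation was 0.359 for lymphocyte, 0.447 for antigen presentation and erythroid, 0.567 for immediate early and ER stress, 0.582 for oxidative phosphorylation and 0.224 for NF-kB genes. The ER stress median was -0.24 with GC and length offsets. The ER stress call was lost without WT saline replicate 2 (camera adjusted p = 0.0809) or Set7KO isoproterenol replicate 2 (0.0515).

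Fibroblast and matrix lists rose by small medians. The extracellular matrix list had a median of 0.23 over 65 members, of which 0 passed adjusted over the list alone; edgeR gave 9 members higher and 1 lower at an unadjusted p under 0.05. Lum, a small leucine-rich proteoglycan, stood at 1.47 ± 0.32 and Postn, a matricellular protein of activated fibroblasts, at 1.46 ± 0.39. Activated fibroblast genes had a median of 0.53, with 3 of 23 higher and 1, Angptl4, lower adjusted over the list alone. Resident fibroblast markers (median 0.17, 1 of 16 higher adjusted over the list alone) and clock genes (median 0.50, 0 of 19, with 4 higher and 3 lower at an unadjusted p under 0.05 in edgeR) were called upward as lists. Without Set7KO saline replicate 2 the extracellular matrix list turned downward (camera adjusted p = 0.747), and the activated fibroblast (0.754) and resident fibroblast (0.770) lists were no longer called. Without WT saline replicate 1 the adjusted p of the 3 lists was 0.0795, 0.0688 and 0.135. The resident fibroblast call was also lost without Set7KO isoproterenol replicate 2 (0.066), and the clock call without Set7KO saline replicate 1 (0.173). With an estimated correlation the adjusted p was 0.707 for extracellular matrix, 0.629 for activated fibroblast, 0.600 for resident fibroblast and 0.582 for clock genes.

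These lists were called by camera with a preset correlation, 13 of 35 lists at an adjusted p under 0.05, from 6.6e-21 for cell cycle genes to 0.0401 for resident fibroblast markers. With an estimated correlation 0 of 35 lists passed, the lowest adjusted p being 0.224 for NF-kB and cytokine genes. The preset was 0.01. In the WT comparison with GC and length offsets the estimate was 0.407 for cell cycle, 0.601 for fatty acid oxidation and 0.944 for erythroid genes. It was lower for NF-kB (0.0345) and Wnt genes (0.00824). For lists whose members vary together, the preset p overstates the evidence. fry called 0 lists. With GC and length offsets camera also called Wnt signalling upward (0.0198) and interferon response genes downward (0.0198), with 0.392 and 0.799 under an estimated correlation.

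In WT alone, 5 genes with the smallest p between isoproterenol and saline were taken for naming. Fbp2 had a log2 fold change of -2.23 ± 0.22 SE, Scd4 of -2.76 ± 0.29, Acot1 of -1.99 ± 0.21, Scgb1c1 of -2.12 ± 0.24 and Angptl4 of -3.81 ± 0.52; none of the 5 passed. Lymphocyte markers fell as a list, 14 of 16 members adjusted over the list alone, with a median of -2.34 and Cd79a at -2.70 ± 0.45. Antigen presentation genes fell, with Cd74, the invariant chain of class II complexes, at -3.15 ± 0.51 and 6 of 14 members lower. Fatty acid oxidation (17 of 35 lower, median -0.64), cell cycle (14 of 42 lower and 1 higher, median -1.20), oxidative phosphorylation (16 of 52 lower and 1 higher, median -0.37), immediate early (4 of 24 lower, median -0.81), erythroid (4 of 8 lower, median -1.23) and cardiomyocyte lists (5 of 16 lower, median -0.42) fell as well. Genes of the sex-linked list rose, 4 of 5 adjusted over the list alone, with the Y-linked Eif2s3y at 1.98 ± 0.48 and Kdm5d at 1.52 ± 0.36. The lowest adjusted p of these 9 lists with an estimated correlation was 0.682. The extracellular matrix list was not called in WT (median -0.20, camera adjusted p = 0.918; median 0.02 and 0.609 with GC and length offsets), with 2 of 65 members, Lum and Cthrc1, higher adjusted over the list alone.

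edgeR called 0 of 17636 genes in WT at an adjusted p under 0.05, with 5599 at an unadjusted p under 0.05 (2583 with GC and length offsets) where 882 were expected by chance, and the lowest adjusted p was 0.0614. limma-voom called 0 and DESeq2 called 2564. The 2 Set7KO saline libraries, which share the estimate of spread, set the edgeR count: leaving out replicate 1 gave 3676 genes and leaving out replicate 2 gave 3765, of which 3536 were in both. With GC and length offsets those counts were 2 and 2, and 2 genes, Fbp2 and Scd4, passed with all 8 libraries. DESeq2 with the same offsets called 419. With these offsets the cardiomyocyte (camera adjusted p = 0.166) and sex-linked (0.0653) list calls were lost, and NF-kB (0.000258) and ER stress genes (0.0227) were called downward, with 0.572 and 0.671 under an estimated correlation. The offsets brought the medians to -0.07 for cardiomyocyte, 0.85 for sex-linked and -0.60 for antigen presentation genes.

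In Set7KO, Cpxm2 had a log2 fold change of 2.35 ± 0.23 SE between isoproterenol and saline, and Scd4 of -2.57 ± 0.29. Ptprn, a secretory granule protein, stood at 1.59 ± 0.21, the Wnt inhibitor Wif1 at 3.02 ± 0.45 and Ahnak2 at 1.83 ± 0.28; none of the 5 passed. Cell cycle genes fell as a list, 5 of 42 members adjusted over the list alone, with a median of -0.84 and Mki67 at -2.80 ± 0.50. Interferon response genes fell, with Oas3 at -2.34 ± 0.59, a median of -0.69 and 3 of 31 members lower. Extracellular matrix genes rose as a list (median 0.45), although 0 of 65 members passed adjusted over the list alone and 10 were higher at an unadjusted p under 0.05 in edgeR, among them Thbs4 (1.21 ± 0.34) and Col14a1 (1.11 ± 0.33). Fatty acid oxidation genes fell (4 of 35 lower, median -0.39), with Pdk4, a kinase that limits glucose oxidation, at -2.80 ± 0.70. Glycolysis genes rose (2 of 23 higher, median 0.42). Over the 14 lists called in Set7KO the lowest adjusted p with an estimated correlation was 0.543.

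Camera also called resident fibroblast (median 0.55), activated fibroblast (0.56), smooth muscle (0.48), oxidative stress (0.16) and Wnt signalling lists (0.03) upward in Set7KO, and erythroid (-1.15), sex-linked (-1.44), neutrophil (-3.07) and NF-kB lists (-0.34) downward. Few members passed adjusted over the list alone: 4 of 5 sex-linked genes lower, 2 of 47 Wnt genes higher, 1 of 23 activated fibroblast genes lower, and none of the 16 resident fibroblast, 14 smooth muscle, 25 oxidative stress, 8 erythroid, 7 neutrophil and 33 NF-kB genes, of which edgeR had 2, 1, 3, 6, 3 and 6 at an unadjusted p under 0.05. edgeR called 0 genes, with 1704 at an unadjusted p under 0.05 (1570 with GC and length offsets), limma-voom called 0 and DESeq2 99; with GC and length offsets edgeR called 0 and DESeq2 137. With the offsets camera also called antigen presentation (0.00621) and immediate early genes (0.0169) downward, both at 0.679 with an estimated correlation, and no longer called Wnt signalling (0.0764). The medians with offsets were 0.27 for glycolysis and -0.87 for sex-linked genes. edgeR called 486 genes without Set7KO saline replicate 1, 1 without Set7KO saline replicate 2 and 2 without Set7KO isoproterenol replicate 2. These calls were lost with an estimated correlation (lowest adjusted p = 0.543), while fry called the NF-kB list (adjusted p = 0.0409). Without Set7KO saline replicate 2 those of the extracellular matrix (0.631), activated fibroblast (0.718), resident fibroblast (0.0696), smooth muscle (0.341), fatty acid oxidation (0.101), erythroid (0.36), neutrophil (0.983), sex-linked (0.0701) and Wnt (0.159) lists were lost. With a filter of 1 CPM in 2 libraries the neutrophil call was lost (0.102). The NF-kB (0.0923) and oxidative stress (0.381) calls were lost without Set7KO saline replicate 1, and without Set7KO isoproterenol replicate 1 the activated fibroblast (0.0573), Wnt (0.203) and sex-linked (0.0573) calls.

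**Figure D4:**
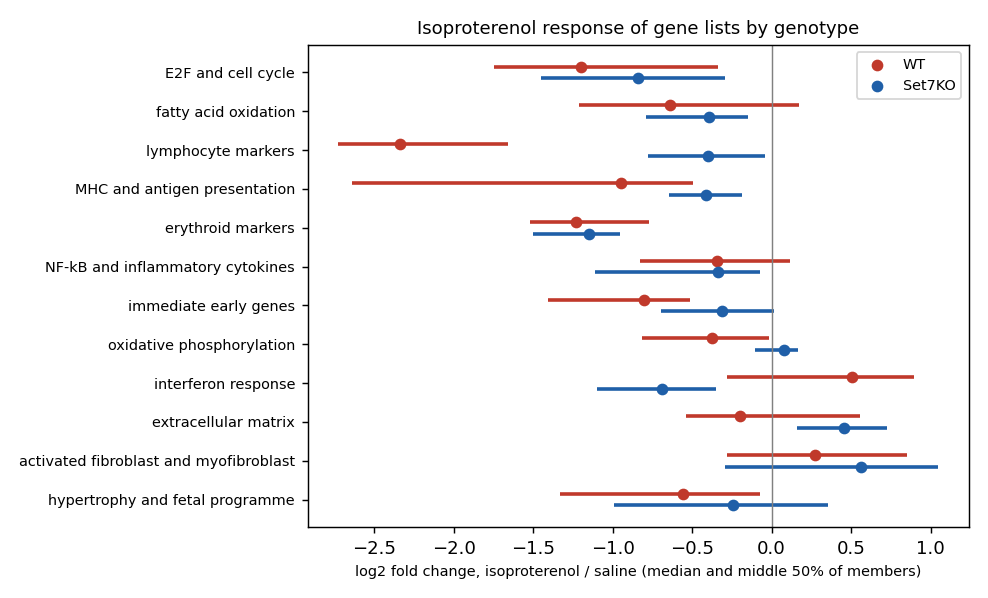
Median log2 fold change between isoproterenol and saline (x axis) of 12 gene lists (y axis) in WT and Set7KO; points are medians over the measured members and lines span the middle 50% of members. The medians of the interferon list (0.51 in WT and -0.69 in Set7KO) and the extracellular matrix list (-0.20 and 0.45) lie on opposite sides of 0; with GC and length offsets, not drawn, those of the extracellular matrix list were 0.02 and 0.43.

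Genes often followed in this model did not pass in any contrast. Averaged over genotypes the natriuretic peptide gene Nppa stood at -0.31 ± 0.52 SE and Nppb at -0.73 ± 0.48, and the slow myosin Myh7 at -0.17 ± 0.13. Skeletal actin Acta1 stood at -1.26 ± 0.72, the fibrillar collagens Col1a1 at 0.14 ± 0.38 and Col3a1 at 0.35 ± 0.38 and elastin Eln at -0.70 ± 0.37. The cell cycle regulator E2f1 ranged from 0.866 to 1.54 CPM in the isoproterenol libraries and from 1.24 to 3.32 CPM in the saline libraries. Ankrd1, a stress-responsive cardiac repeat protein, ranged from 1900 to 3020 CPM in the isoproterenol libraries and from 407 to 1240 CPM in the saline libraries (log2 fold change 1.49 ± 0.36, not past the threshold over all genes). Levels of Nppa within a group differed widely, at 1610 and 306 CPM in the WT saline libraries. Wnt10a had 0 counts in each library, which allows a level of up to 0.0598 to 0.112 CPM depending on the library. The hypertrophy list did not pass for isoproterenol averaged over genotypes (camera adjusted p = 0.126), nor did TGF-beta (0.467) or Wnt signalling (0.193; 0.0198 with GC and length offsets, and 0.392 with these and an estimated correlation).

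The response to isoproterenol was compared between genotypes by the interaction. For lymphocyte markers the response in Set7KO minus that in WT was positive (median 1.73, 4 of 16 members adjusted over the list alone), with Cd79a at 2.61 ± 0.61 SE and Igkc at 2.31 ± 0.57. The list had a median of -2.34 in WT and -0.40 in Set7KO, where it was not called, so the positive difference reflected a smaller median decrease. The same held for antigen presentation genes (median difference 0.74, 4 of 14 members), at -0.95 in WT and -0.41 in Set7KO, with Cd74 at 2.47 ± 0.68. For interferon response genes the difference was negative (median -1.34, 11 of 31 members), with list medians of 0.51 in WT (0.23 with GC and length offsets) and -0.69 in Set7KO, and with Ifit2 at -2.92 ± 0.52 and Ifit3 at -2.06 ± 0.43. It was negative for the sex-linked list too (median -3.43, 4 of 5 members), and positive for oxidative phosphorylation (0.45), glycolysis (0.78, 9 of 23 members positive and 1 negative), cardiomyocyte (0.69), extracellular matrix (0.66) and immediate early genes (0.75). Of the extracellular matrix list 0 of 65 members passed adjusted over the list alone, and the 4 members with the smallest p at a mean of at least 1 CPM went the other way: Lum stood at -2.31 ± 0.63, Ogn at -3.01 ± 0.90, Plod2 at -1.90 ± 0.54 and Dcn at -1.73 ± 0.58. Each of the 9 lists had an adjusted p of 0.845 with an estimated correlation. The extracellular matrix call was lost without WT saline replicate 2 (camera adjusted p = 0.0984), Set7KO saline replicate 2 (0.433) or Set7KO isoproterenol replicate 1 (0.116), and the immediate early call without WT saline replicate 1 (0.164) or Set7KO saline replicate 2 (0.301).

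edgeR called 0 genes for the interaction, with 5400 at an unadjusted p under 0.05 (2211 with GC and length offsets); limma-voom called 0 and DESeq2 2098. Among the genes with the smallest p, Mndal (-3.39 ± 0.49), Clock (-3.36 ± 0.49), Cenpj (-3.11 ± 0.47) and Kctd12b (-3.06 ± 0.47) did not pass. Without Set7KO saline replicate 1 edgeR called 5778 genes, without replicate 2 of that group 1, and with GC and length offsets on all 8 libraries 0; the offsets brought the DESeq2 count to 185. With the offsets the glycolysis (camera adjusted p = 0.186), immediate early (0.242) and cardiomyocyte (0.168) list calls were lost, at medians of 0.27, 0.16 and 0.24. The medians of the interaction with offsets were -1.73 for sex-linked, 0.24 for oxidative phosphorylation, 0.40 for extracellular matrix and 0.34 for antigen presentation genes. Across genes the responses of the 2 genotypes had a Pearson correlation of -0.259 and a Spearman correlation of -0.415, with 31.1% of genes of the same sign; without Set7KO saline replicate 2 the Pearson correlation was 0.073, and with GC and length offsets -0.0547.

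After saline, Setd7 was the gene that differed between Set7KO and WT (log2 fold change -3.09 ± 0.24 SE, adjusted p = 0.0163). Neutrophil markers were higher in Set7KO as a list, 6 of 7 members adjusted over the list alone, with a median of 4.37. The member S100a9 stood at 65.7 CPM in Set7KO saline replicate 2 and 4.19 CPM in replicate 1. In the WT saline libraries S100a9 was at 0.896 and 2.45 CPM. Erythroid markers (median 0.98, 0 of 8 members), interferon response genes (0.45, 0 of 31) and sex-linked genes (1.53, 4 of 5) were also higher as lists. Atrial (-1.79), immediate early (-0.34), antigen presentation (-0.31), extracellular matrix (-0.30), ion channel (-0.26), smooth muscle (-0.41), hypertrophy (-0.36) and cardiomyocyte lists (-0.27) were lower, with 1 member of the hypertrophy list, Xirp2 (1.45 ± 0.33), higher adjusted over the list alone. Il1b, an inflammatory cytokine, was at 2.60 and 2.71 CPM in the Set7KO saline libraries and at 0.485 and 0.331 CPM in the WT saline libraries. Over the 12 lists called after saline the lowest adjusted p with an estimated correlation was 0.751.

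In edgeR 1815 genes were at an unadjusted p under 0.05 after saline, and 1007 with GC and length offsets. The Setd7 call was lost, with a count of 0, without WT saline replicate 1 (adjusted p = 0.266) or 2 (0.199), WT isoproterenol replicate 1 (0.0991) or 2 (0.104), or Set7KO isoproterenol replicate 1 (0.103) or 2 (0.0954). The count was 1030 without Set7KO saline replicate 1 and 2 without replicate 2, limma-voom called 1 gene and DESeq2 20. With GC and length offsets edgeR called 1 gene, Setd7, and DESeq2 9. Without Set7KO saline replicate 2 the extracellular matrix list was higher instead of lower (camera adjusted p = 0.0319), the hypertrophy (0.798), immediate early (0.798) and antigen presentation (0.847) lists turned upward without a call, and the cardiomyocyte (0.0767), smooth muscle (0.577) and erythroid (0.547) calls were lost. The ion channel (0.382), interferon (0.364), cardiomyocyte (0.158) and atrial (0.283) calls were lost without Set7KO saline replicate 1. Without WT saline replicate 1 the atrial list turned upward (0.931), and the hypertrophy (0.248), interferon (0.102), immediate early (0.192), smooth muscle (0.248) and erythroid (0.0587) calls were lost. Without WT saline replicate 2 the extracellular matrix (0.257), ion channel (0.368), antigen presentation (0.400) and cardiomyocyte (0.400) calls were lost, as were the hypertrophy (0.126), ion channel (0.175) and cardiomyocyte (0.395) calls with GC and length offsets, and the cardiomyocyte call with a filter of 1 CPM in 2 libraries (0.0648). The offsets brought the medians to -0.17 for extracellular matrix, -0.13 for immediate early, -0.19 for hypertrophy, -0.05 for ion channel, -0.10 for cardiomyocyte and 0.80 for sex-linked genes.

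After isoproterenol, Setd7 was again the gene that differed between Set7KO and WT (log2 fold change -4.08 ± 0.25 SE, adjusted p = 0.00256). Lymphocyte markers were higher in Set7KO, 11 of 16 adjusted over the list alone, with a median of 1.76, Trbc2 at 2.24 ± 0.50 and Cd79a at 1.96 ± 0.45. Glycolysis genes were higher (median 0.51, 9 of 23 higher and 1 lower), with Eno3, a muscle enolase, at 0.89 ± 0.20. Erythroid genes were higher (1.28, 4 of 8), as were oxidative phosphorylation (0.36), antigen presentation (0.45), cardiomyocyte (0.43) and macrophage lists (0.28), of which 0 members passed adjusted over the list alone. Interferon response genes were lower (median -0.78, 11 of 31), with Ifit2 at -1.95 ± 0.37 and Ifit1 at -1.86 ± 0.48, and so were sex-linked (-1.89, 4 of 5) and histone lysine methyltransferase and demethylase genes (-0.31, 0 of 37). The extracellular matrix list was not called (median 0.36, camera adjusted p = 0.0879), and Postn stood at -1.27 ± 0.55; the list was higher without WT isoproterenol replicate 1 (0.0405), Set7KO saline replicate 1 (0.00511) or 2 (0.00434), or Set7KO isoproterenol replicate 2 (0.00609), and with GC and length offsets (0.0234). The offsets also brought camera calls of higher endothelial (0.013), NF-kB (0.00698), resident fibroblast (0.0234) and oxidative stress lists (0.0237), of which the lowest adjusted p with an estimated correlation was 0.733. Their medians became smaller with the offsets. They went from 0.308 to 0.24 for endothelial, 0.175 to 0.153 for NF-kB, 0.664 to 0.225 for resident fibroblast and 0.185 to 0.119 for oxidative stress genes. With an estimated correlation the lowest adjusted p over the 10 lists called after isoproterenol was 0.769.

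edgeR called 1 gene after isoproterenol, with 3505 at an unadjusted p under 0.05 (1314 with GC and length offsets); limma-voom called 1, DESeq2 267, and edgeR on these 2 groups alone 1303. With GC and length offsets edgeR called 1 gene, Setd7, and DESeq2 44. Without Set7KO isoproterenol replicate 1 the edgeR count was 0 (Setd7 adjusted p = 0.150), and without replicate 2 of that group it was 2, Setd7 not among them (0.0510). The histone methylation call was lost without WT saline replicate 1 (camera adjusted p = 0.0506) or 2 (0.0585), WT isoproterenol replicate 2 (0.105) or Set7KO isoproterenol replicate 2 (0.140), and with the offsets (0.230). The macrophage call was lost without WT isoproterenol replicate 2 (0.197) or Set7KO isoproterenol replicate 2 (0.118), the interferon call without WT isoproterenol replicate 2 (0.325), the erythroid (0.0602) and sex-linked (0.0593) calls without Set7KO isoproterenol replicate 1, and the cardiomyocyte call with the offsets (0.0938). The offsets brought the medians to 0.10 for antigen presentation, 0.27 for glycolysis, 0.15 for cardiomyocyte, 0.20 for extracellular matrix, -0.06 for histone methylation and -0.92 for sex-linked genes.

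Averaged over treatments, Setd7 was the gene called between the genotypes, with 276 genes at an unadjusted p under 0.05 in edgeR (345 with GC and length offsets). Erythroid markers were higher in Set7KO, 8 of 8 members adjusted over the list alone, with a median of 1.15, Hba-a2 at 1.06 ± 0.27 SE and Hbb-bs at 1.15 ± 0.29. After saline the globin gene Hba-a1 stood at 2270 CPM in Set7KO replicate 2 but 978 CPM in replicate 1, against 901 and 1030 CPM in WT. After isoproterenol it was at 1040 and 632 CPM in Set7KO and 357 and 296 CPM in WT. Neutrophil markers were higher (6 of 7, median 2.59), with the receptor gene Csf3r at 1.57 ± 0.43. The highest levels were in Set7KO saline replicate 2, where Csf3r stood at 13.2 CPM, against 3.13 to 4.21 CPM in the other Set7KO libraries and 1.13 to 2.54 CPM in WT; without that library the camera adjusted p of the list was 0.000233. Lymphocyte (median 0.76, 0 of 16), macrophage (0.32, 0 of 19), NF-kB (0.06, 1 of 33), oxidative phosphorylation (0.18, 0 of 52) and glycolysis lists (0.15, 0 of 23) were higher. The member of the NF-kB list that passed adjusted over the list alone was Il1b, at 1.85 ± 0.32. Atrial (-1.21, 0 of 9), beta-adrenergic and calcium handling (-0.06, 0 of 34), histone methylation (-0.14, 0 of 37) and hypertrophy lists (-0.09, 0 of 20) were lower. With an estimated correlation the lowest adjusted p over these 11 lists was 0.236, shared by erythroid, neutrophil and NF-kB genes.

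limma-voom called 1 gene between the genotypes averaged over treatments and DESeq2 2; with GC and length offsets the counts were 1 in edgeR and 2 in DESeq2. Without Set7KO saline replicate 2 or Set7KO isoproterenol replicate 2 edgeR called 2 genes, Setd7 among them. The atrial call was lost without WT saline replicate 1 (camera adjusted p = 0.306) or WT isoproterenol replicate 2 (0.159), and the glycolysis call without WT saline replicate 1 (0.155). The hypertrophy list turned upward without Set7KO saline replicate 2 (0.688), and its call was lost without WT saline replicate 1 (0.244), WT isoproterenol replicate 2 (0.0787), Set7KO isoproterenol replicate 1 (0.123) or Set7KO isoproterenol replicate 2 (0.0713). The beta-adrenergic call was lost without WT saline replicate 2 (0.423), WT isoproterenol replicate 2 (0.0771), Set7KO saline replicate 1 (0.755) or Set7KO isoproterenol replicate 2 (0.704), and with the offsets (0.0656). The histone methylation call was lost without WT saline replicate 1 (0.155) or 2 (0.0663), WT isoproterenol replicate 2 (0.109), Set7KO saline replicate 1 (0.483) or Set7KO isoproterenol replicate 2 (0.287), and with the offsets (0.685). The medians with offsets were -0.03 for beta-adrenergic, 0.16 for NF-kB and 0.00 for histone methylation genes.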

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

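Of the tests below, those of GC content on the principal component and on the WT calls, of a wrong treatment, the libraries left out of the clock test and the GC and length offsets were chosen only after the result was seen; those of depth, clock phase and other splits were chosen before. The GC test on the principal component first used the correlation of loadings with GC content and was rewritten after results were seen.

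The isoproterenol response of 9 gene lists differed between Set7KO and WT in the interaction test (camera with the preset correlation). The adjusted p was 4.61e-05 for lymphocyte markers, 0.000137 for interferon response, 0.000256 for sex-linked genes, 0.00239 for oxidative phosphorylation, glycolysis and antigen presentation, 0.00899 for cardiomyocyte markers, and 0.0191 for extracellular matrix and immediate early genes. With an estimated correlation the adjusted p of each was 0.845. Single libraries standing apart were not tested, because a group of 2 does not show which of its libraries stands apart.

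Set7KO saline replicate 2 lay with the WT isoproterenol libraries on the first principal component, at 61.8. After thinning to the smallest library its score was 61.6, against depth as the cause. With GC and length offsets it was 38.2, beside 39.2 and 39.8 in WT isoproterenol. That is against these trends, as the offsets model them, as the whole cause. Whether the component still followed GC content after the offsets was not checked, so bias that the offsets missed stays open. A wrong treatment stays open: of the 42 genes called for isoproterenol averaged over genotypes without this library it was nearer to the saline mean at 22, and with offsets at 6 of 9, while its levels of Cpxm2 (23.3 CPM) and Scd4 (7.77 CPM) lay with the saline libraries, in genes called with it in that group. No biological explanation was tested, since the design gives none for a single library of a group.

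Leaving out Set7KO saline replicate 2 gave 3765 genes called for isoproterenol in WT, with median GC content of 43.4% in risen and 56.8% in fallen genes. With offsets their median absolute log2 fold change was 0.372 of its size, from 1.16 to 0.43, and the median SE went from 0.27 to 0.21, so the calls, 2 excepted, ended because the fold changes shrank. GC and length bias is a candidate explanation for most of these calls. The offsets also remove any response to isoproterenol that follows GC content, which in WT has the same direction, so the share of a biological response could not be separated.

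The 9 genes called for isoproterenol averaged over genotypes were weighed against clock phase at collection. With the difference of log2 Dbp and Arntl as a covariate, their fold changes had a median ratio of 0.955 to those without it. Over the genes the ratio ranged from 0.891 to 1.10, and the median lay between 0.951 and 1.16 with 1 library left out. This is only weak evidence against clock phase as the whole cause of these differences. Most of the within-group spread of the index lies between the 2 WT saline libraries. A gene that followed the index would differ between them and would hardly have been called, so ratios near 1 were favoured by the choice of genes. edgeR called 0 genes with the covariate, each of the 9 being at an unadjusted p under 0.05, as their median SE went from 0.20 to 0.25, so the calls themselves were not kept. Of the within-group spread of the index 90.4% came from the 2 WT saline libraries, and without WT saline replicate 1 the ratio of single genes ranged from 0.752 to 1.68, so a partial contribution stays open. Clock phase was not tested for the gene lists, whose medians moved with the covariate from -0.40 to -0.28 for fatty acid oxidation and from -0.98 to -0.43 for cell cycle genes.

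Of the 35 splits of the 8 libraries into 4 and 4, 2 gave as many genes as the real treatment split (3 genes in a model of 2 groups), the real split included, and 5 gave as many as the real genotype split (1 gene). Among those 5 were the real treatment split and the highest other split, which called 5383 genes. By these tallies chance is not excluded for the number of genes called for either factor. The gene of the genotype split was Setd7, on which a tally of other genes says nothing: its level in the 4 Set7KO libraries lay below that in the 4 WT libraries (log2 fold change -3.59). The split with 5383 genes set both WT saline libraries, Set7KO saline replicate 1 and Set7KO isoproterenol replicate 2 against the rest, which follows the GC trend and the first principal component and points to a structure of the samples other than the design.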

How the results depend on the processing

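Of the alternatives below, the GC and length offsets, alone, with a library left out or in DESeq2, were chosen only after the result was seen; the others were planned. No paired analysis was possible because the labels give no shared replicate numbers. In the text WT means isoproterenol against saline in WT, KO the same in Set7KO, saline and isoproterenol the genotype difference in each treatment, and all counts are of genes past the threshold. Over the alternatives run for named genes, 5279 of their values stayed on their side of the threshold, 69 of them with the sign turned. Another 422 gained a call and 43 lost it. List values were followed for lists called in the primary analysis, and for extracellular matrix in WT and isoproterenol, where it was not called. Of these 789 stayed on their side, 3 of them with the sign turned, 239 lost the call, 5 gained it and 7 reversed. Calls gained by other lists are not in this tally, and some alternatives, such as upper quartile and limma-voom, were run for counts only. Of the counts, 83 stayed within 1.5 times that of the primary analysis and 63 moved. Groups of 2 libraries limit each comparison, and transcripts under 0.0598 to 0.112 CPM were below the floor.

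With size factors of DESeq2 the WT count was 3, and with a filter of 1 CPM in 2 libraries 3. With no filter the counts were 1512 (WT), 31 (KO), 19 (saline), 3 (isoproterenol), 1686 (interaction), 159 (treatment averaged) and 2 (genotype averaged). On the 2 groups alone they were 5043 (WT), 0 (saline, edgeR, with 1815 genes at an unadjusted p under 0.05 in the fit of all libraries, 1 in limma-voom and 20 in DESeq2) and 1303 (isoproterenol). The additive model gave 1 gene for treatment averaged and limma-voom 14. DESeq2 gave 2564, 99, 20, 267, 2098, 235 and 2 in the order above, and with GC and length offsets 419, 137, 9, 44, 185, 359 and 2. edgeR with these offsets gave 2 for WT and 14 for treatment averaged. With Set7KO saline replicate 1 or 2 also left out, that group held a single library. In both of these fits the Setd7 call for saline was lost, and only some of the 9 genes of the primary analysis were kept for treatment averaged. The cause of these differences was not tested, except that fewer libraries, and no filter, change the estimate of spread and the number of genes tested by construction.

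Leaving out 1 library at a time gave 0 to 3765 genes in edgeR for WT (highest without Set7KO saline replicate 2, and 3676 without replicate 1), 0 to 486 for KO and 0 to 1030 for saline (each highest without Set7KO saline replicate 1), 0 to 2 for isoproterenol (0 without Set7KO isoproterenol replicate 1, 2 without replicate 2), 0 to 5778 for the interaction (highest without Set7KO saline replicate 1), 0 to 42 for treatment averaged (highest without Set7KO saline replicate 2) and 1 to 2 for genotype averaged. With all libraries edgeR had 5599 (WT), 1704 (KO) and 5400 (interaction) genes at an unadjusted p under 0.05, and the counts of limma-voom were 0 in these 3. The correlation of the responses ranged from -0.334 to 0.073, reversed without Set7KO saline replicate 2, and was -0.0547 with GC and length offsets. The adjusted p of the extracellular matrix list for the interaction, 0.0191 in camera, was 0.845 with an estimated correlation and 0.707 in fry, and ranged from 4.25e-08 to 0.433 with 1 library left out. For isoproterenol it was 0.0234 with the offsets and ranged from 0.00434 to 0.619 with 1 library left out. Lists that reversed are given with the lowest and highest adjusted p of camera over the libraries left out. Without WT saline replicate 1 atrial markers for saline reversed (0.931; 2.8e-07 to 0.931). Without Set7KO saline replicate 2, hypertrophy (0.798; 0.000332 to 0.798), extracellular matrix (0.0319; 1.14e-12 to 0.257), antigen presentation (0.847; 2.71e-06 to 0.847) and immediate early genes (0.798; 1.84e-07 to 0.798) reversed for saline. So did extracellular matrix for treatment averaged (0.747; 4.61e-23 to 0.747) and hypertrophy for genotype averaged (0.688; 1.51e-08 to 0.688). The cause was not tested.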

Other observations

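Atrial genes differed between libraries of the same group. Myl7, an atrial myosin light chain, was at 445 CPM in WT saline replicate 1, 97.1 CPM in WT isoproterenol replicate 2 and 58.0 CPM in Set7KO saline replicate 1, and at most 5.30 CPM in the other 5 libraries. Myl4 was at 484, 114 and 69.6 CPM in the same 3 libraries, and Sln, which regulates calcium uptake in atria, at 90.3, 26.0 and 5.88 CPM. Y-linked genes were present in each library, and Xist was at 0 to 0.299 CPM. Ddx3y was at 11.6 and 12.6 CPM in the WT isoproterenol libraries and 14.2 CPM in Set7KO saline replicate 2, and between 0.762 and 4.03 CPM in the other 5. Kdm5d was at 10.9, 11.9 and 11.9 CPM in these libraries and between 3.88 and 5.75 CPM in the others. This is the split of the first principal component, from which the calls of the sex-linked list cannot be told apart.

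The test of atrial tissue, and its repeat without Nppa, were chosen only after the Nppa values were seen. Over the 8 libraries the other 8 measured atrial markers had a median Spearman correlation with Myl7 of 0.627, against a 95th percentile of 0.226 for random lists matched on expression. Nppa is itself one of these markers, and without it the median was 0.563, against 0.238 for random lists. Kcnj3 (-0.119) and Gja5 (0.0238) did not follow Myl7, while the other tested markers lay between 0.548 for Stard10 and 1 for Myl4. Bmp10, also on the list, was removed by the filter. It had 29 counts in Set7KO saline replicate 2, where Myl7 was at 2.77 CPM, and 0 in each other library, those with high Myl7 included. A different amount of atrial tissue in the samples is a candidate explanation for part of the spread of Nppa within groups, and no dissection record was available here to test it. In Set7KO isoproterenol Nppa stood at 567 and 231 CPM with Myl7 at only 4.25 and 0.878 CPM. In WT isoproterenol replicate 2 a like Nppa level, 569 CPM, came with Myl7 at 97.1 CPM. The spread of Nppa in Set7KO isoproterenol is thus not matched by a like level of Myl7. The cardiac chambers taken are not stated in the labels.

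Clock genes also differed within groups. Arntl was at 0.896 CPM in WT saline replicate 1 and 18.0 CPM in replicate 2, and Dbp at 378 and 47.6 CPM. In the Set7KO saline libraries Arntl was at 15.5 and 6.38 CPM, and in the 4 isoproterenol libraries between 1.13 and 2.54 CPM. The time of collection is not given in the labels.

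The gene CT010467.1, which holds ribosomal RNA sequence, took 6.10% of counts in WT saline replicate 1 and 4.53% in Set7KO saline replicate 2, and 0.238% to 2.11% in the other 6 libraries. Mitochondrial genes took 1.85% and 2.12% in WT saline, 5.75% and 4.41% in WT isoproterenol, 3.02% and 3.81% in Set7KO saline, and 3.15% and 3.43% in Set7KO isoproterenol. Within 5 Mb of Setd7, edgeR called 0 of 39 tested genes for genotype averaged over treatments, 0 were at an unadjusted p under 0.05, and the largest absolute log2 fold change at 2 CPM or more was 0.56, for Postn. The title of Set7KO saline replicate 2 carries the same group letter as the WT saline titles, while its Setd7 level, 5.70 CPM, was above the 3.79 to 4.45 CPM of the other 3 Set7KO libraries and below the 43.0 to 72.6 CPM of the WT libraries.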
